A study of Mus musculus with 12 samples.

How the data were processed

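Per the labels, total RNA from mouse spleen was turned into biotin-labelled cDNA with Affymetrix whole-transcript kits for synthesis and terminal labelling and read on Affymetrix arrays. The extraction protocol given with the samples opens with a sentence on mutants of an unrelated gene, which was read as out of place and not used. The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made by RMA in Affymetrix Expression Console, whose versions are not given. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a set. The values lie between 1.33 and 13.79, which was checked as a log2 range. The table holds 12 columns, 1 per sample, all used.

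Groups follow the labels: septic TLR-deficient, septic wildtype and untreated wildtype, with 4 arrays each. Of the probe sets, 21789 carry 1 gene symbol, 1621 several and 12147 none. Each gene was represented by its probe set with the highest mean over the arrays, among those with 1 symbol, which left 19938 genes, and no filter on dim genes was applied. Symbols were matched by gene identifier to a reference table of the mouse genome for 21698 probe sets, used for gene names and for the order of genes along chromosomes. No reads were aligned.

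The 3 comparisons were tested with limma 3.58.1 in R 4.3.3: 1 mean per group fitted over all 12 arrays, moderated variances, two-sided tests and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. A difference is the mean log2 value of the first group named minus that of the second, and SE is its standard error in this fit. In addition, 30 gene lists (793 genes, 710 of them measured, between 9 and 37 in a list) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 90 list tests, and again with an estimated correlation and with limma's fry. Each list also got a score per array, the mean over members of log2 value minus the gene's mean over 12 arrays, compared by exact two-sided permutation over the 70 arrangements of 4 against 4. Myd88 and Ticam1 were compared by the same exact test. The share of the septic response kept was computed over 36 splits that select genes on some wildtype arrays and take the ratio on the others. Genes within 50 places of Myd88 or Ticam1 were to be compared with the rest by Fisher's exact test, which with 0 genes called can give only 1 value and is not reported.

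Groups, comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule was to name, in each comparison, the genes with the largest differences among those past the threshold whose labelled groups do not overlap, with Myd88 and Ticam1 always. No gene met it. The other genes named were therefore chosen after their values were seen, from among the largest differences in a fit without septic wildtype replicate 2 (6 per direction, and 5 in the comparison of septic TLR-deficient with untreated arrays) and from members of the lists, so their values illustrate the comparisons and are not independent evidence.

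The alternatives fixed beforehand were a further quantile normalization, centring each array on its median, filters at percentiles 25 and 50, the mean of a gene's probe sets, every probe set on its own, only the arrays of the groups compared, trended and robust variances, array weights, the replicate number as a block, leaving out each array in turn and a threshold of 0.01. A covariate for Y-linked transcripts, replicates 1 to 3 only, and replicates 1 to 3 without septic wildtype replicate 2 were added after seeing the data. The planned simulation of the overlap between comparisons was not run, because no gene passed in either. No sample was left out of the values reported unless the sentence says so, and no sample was moved to another group.

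The procedure was tested on simulated data with the same number of arrays and 19938 genes, 200 of them changed. It recovered 82.1% to 88.1% of 4-fold changes and 98.5% to 100% of 8-fold changes in the 3 comparisons, and 32.8% to 43.3% of 2-fold changes. In these simulations 13, 10 and 8 unchanged genes were called as well. Simulated data without change gave 0 calls. The simulation drew the noise of each gene independently and shifted all arrays of a group alike, with no array standing apart. The real arrays differ from this, so the recovery rates do not carry over to them. A count of 0 genes in the data therefore excludes no change of these sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.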

Results

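The data describe gene expression in the spleens of C57BL/6 mice, measured on 12 Affymetrix arrays that the labels place in 3 groups of 4 biological replicates. Mice labelled septic underwent colon ascendens stent peritonitis, an operation in which a stent through the wall of the ascending colon lets gut bacteria leak into the abdomen. The labels describe the animals as TLR-deficient and septic, wildtype and septic, or wildtype and untreated. The titles of the TLR-deficient samples name the adaptor proteins Trif and MyD88, through which Toll-like receptors (TLRs) pass on the detection of microbial molecules. There is no group of untreated TLR-deficient mice. The titles carry running numbers, and those of the untreated samples also carry a time point. For the septic mice the time between operation and sampling is not stated in the labels. The values are on a log2 scale and gave 19938 genes for testing. The median log2 value per array lay between 5.22 and 5.54. The number of arrays limits the precision of each value.

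Across genes, which are not independent replicates, 11 of the arrays correlated with each other at Pearson's r of 0.956 to 0.991. The array labelled septic wildtype replicate 2 correlated with the others at only 0.765 to 0.809, and the standard deviation of its log2 values was 1.52 against 2.11 to 2.24 on the other arrays. The labelled groups did not describe the likeness of the arrays: 5 of the 12 arrays were most correlated with an array of their own labelled group. The array labelled untreated replicate 4 was most correlated with septic TLR-deficient replicate 1, septic TLR-deficient replicate 4 with septic wildtype replicate 1, and septic wildtype replicate 4 with untreated replicate 1. Sex-linked transcripts also divided the labelled groups. Xist, the RNA that silences one X chromosome in female cells, was at a log2 value of 3.73, 4.33 and 4.06 on the arrays labelled untreated replicates 1, 2 and 3 and at 4.33 on the array labelled septic wildtype replicate 4. On the array labelled untreated replicate 4 Xist stood at 9.91, and on the remaining septic arrays it ranged from 8.94 to 10.94. The Y-linked gene Eif2s3y, which encodes a subunit of a translation initiation factor, ran the other way, at 7.69 on septic wildtype replicate 4 and 2.55 on untreated replicate 4. The labels give no sex. Because the arrays did not group by label, every group name stands for what the labels say and not for a condition established from the values.

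**Figure D1:**
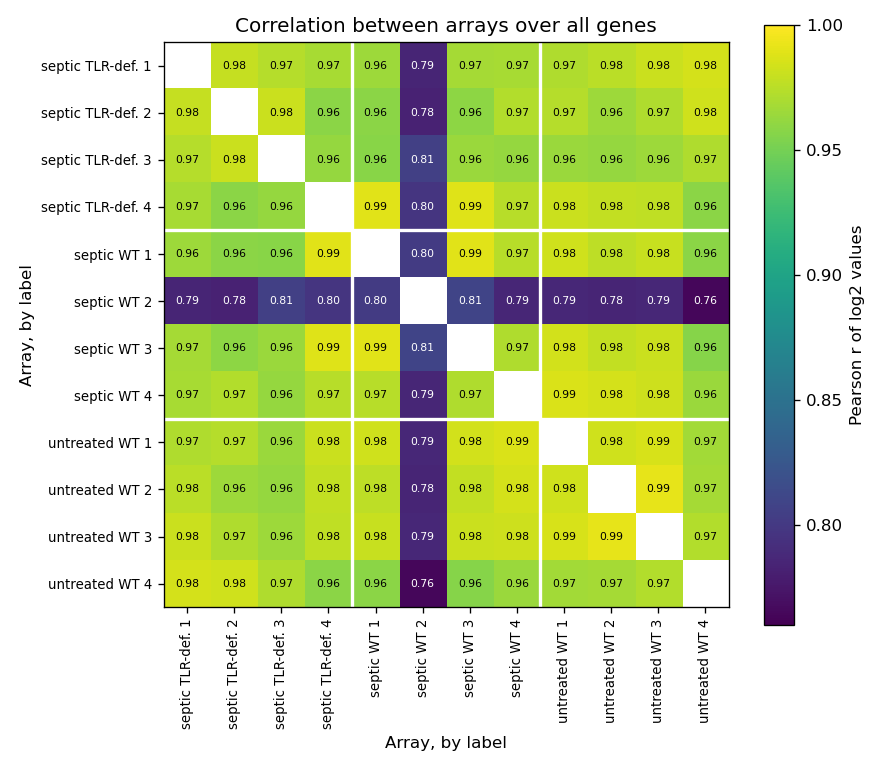
Pearson's r of log2 values over all genes for each pair of the 12 arrays, ordered by label, with white lines between the labelled groups and the colour scale running from low to high r. Septic wildtype replicate 2 lies at 0.765 to 0.809 with the other arrays, and replicate 4 of each group resembles arrays of another group more than its own.

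Values of the TLR adaptors were compared between the groups, with no test of whether they lie above background. Myd88, which encodes the adaptor shared by most TLRs, had a mean log2 value of 9.28 ± 0.45 (SD, n = 4) on the arrays labelled septic TLR-deficient, 8.29 ± 1.23 (SD, n = 4) on those labelled septic wildtype and 9.27 ± 0.37 (SD, n = 4) on those labelled untreated. Ticam1, which encodes Trif, averaged 5.88 ± 0.06, 6.01 ± 0.26 and 6.25 ± 0.35 (SD, n = 4 each) in the same order. Between septic TLR-deficient and septic wildtype arrays the exact two-sided permutation test gave p = 0.114 for Myd88 and p = 0.400 for Ticam1, and the adjusted values over the 6 tests of both genes were 0.286 and 0.480. The value of 6.48 on septic wildtype replicate 2 was the lowest for Myd88, and the other 11 arrays lay between 8.62 and 9.75. The alleles are not stated in the labels, so these probe sets may lie outside the deleted part of each gene. Among the 200 genes nearest to Myd88 and Ticam1 on their chromosomes, 0 differed between the septic groups in limma, with 14 at an unadjusted p under 0.05. No gene elsewhere differed either, so the planned comparison of these genes with the rest could show nothing.

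As labelled, the comparison of septic with untreated wildtype spleens asks what the peritonitis does in animals with intact TLR signalling. Whether the arrays hold those conditions is not established from the values. All 31 measured type I interferon-stimulated genes, an antiviral program that cells switch on when they sense interferon, had lower means on the arrays labelled septic wildtype. Their median log2 difference was -1.70, with adjusted p = 1.44e-17 in limma's camera and adjusted p = 0.415 with an estimated correlation. Ifit1, an interferon-induced protein that binds viral RNA, averaged 7.24 ± 2.38 (SD, n = 4) on the arrays labelled septic wildtype and 10.24 ± 0.86 (SD, n = 4) on those labelled untreated. Cxcl10, a chemokine that draws T cells, averaged 9.58 ± 1.45 against 11.90 ± 0.88 (SD, n = 4 each), a difference of -2.32 (SE 0.70, adjusted p = 0.439). This direction was not shared by every array, since the one labelled septic wildtype replicate 4 had Ifit1 at 10.21 and the other 3 arrays of its group at 7.45, 4.42 and 6.88.

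No single gene differed between these groups at an adjusted p under 0.05 in limma (0 of 19938), while 1756 had an unadjusted p under 0.05 where 997 would be reached by chance. That count rests on single arrays: it was 848, 793 and 858 without untreated replicate 2, 3 or 4, 1086, 3038 and 3193 without septic wildtype replicate 2, 3 or 4, and 761 with Y-linked transcripts as a covariate, an alternative chosen after seeing the data. The lowest adjusted p was 0.439. In 1280 genes (6.42%) the 4 arrays of one label all lay above the 4 of the other, which chance gives for 2.86%. Irf7, the transcription factor that amplifies interferon production, had a difference of -1.93 (SE 0.75; -1.24 without septic wildtype replicate 2), and Mx2, a GTPase that restricts viruses, of -2.40 (SE 0.80). Slfn4, an interferon-responsive gene of myeloid cells, had a difference of -1.98 (SE 0.93; -3.05 without septic wildtype replicate 4). Among genes outside the lists of interferon-stimulated genes, Serpina3n, a secreted protease inhibitor of the acute-phase response, averaged 8.01 ± 1.84 against 10.98 ± 0.19 (SD, n = 4 each), a difference of -2.97. Saa3, an acute-phase protein made by macrophages and stroma, had a difference of -2.13 (SE 1.26), Acod1, which makes the antimicrobial metabolite itaconate, of -2.12 (SE 1.01), and Lox, which crosslinks collagen, of -1.98 (SE 0.77). Ifit3b, a relative of Ifit1, had a difference of -2.63 (SE 0.81). Higher means on the arrays labelled septic wildtype were found for Adgre1, a surface receptor that marks mature macrophages, with 1.35 (SE 0.74; 0.81 and 2.04 without septic wildtype replicate 3 or 4), and for Fcer2a, the low-affinity IgE receptor of follicular B cells, with 1.11 (SE 0.96; 0.41 without untreated replicate 4 and 0.69 without septic wildtype replicate 1). Each of these genes had an adjusted p of 0.439 or more. With replicates 1 to 3 of each group only, an alternative chosen after seeing the data that leaves out arrays standing apart and so favours calls, 9 genes passed, 1 higher (Xist) and 8 lower, the Y-linked genes Kdm5d, Uty and Eif2s3y among them.

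Of the 30 gene lists, camera called 14 lower and 1 higher on the arrays labelled septic wildtype than on those labelled untreated. Genes of interferon-gamma-induced GTPases and antigen processing had a median difference of -1.16 (adjusted p = 1.07e-08, and 0.415 with an estimated correlation), with Gbp5 at -2.19 and Iigp1 at -2.29 (-1.50 without septic wildtype replicate 2), both GTPases that attack vacuoles holding microbes. NF-kappaB feedback and target genes, which the main inflammatory transcription factor induces, were lower in all 25 members, with a median of -0.82 (adjusted p = 1.11e-09, and 0.415 with an estimated correlation). Glucocorticoid-responsive genes had a median of -0.90, chemokines -0.84, apoptosis genes -0.58, inflammatory cytokines -0.53 and TLR pathway components -0.52. The medians were -0.47 for hypoxia and glycolysis genes, -0.44 for coagulation, fibrinolysis and complement genes and -0.42 for unfolded protein response and heat shock genes. Without septic wildtype replicate 2 the medians were -0.65 for the interferon-gamma list, -0.53 for NF-kappaB targets, -0.29 for TLR pathway components, -0.28 for coagulation genes, -0.24 for apoptosis genes and -0.23 for the unfolded protein response. Chemokines had -0.39 and coagulation genes -0.29 without untreated replicate 4, and inflammatory cytokines -0.35 without untreated replicate 2. Plasma cell genes, stromal and endothelial genes and oxidative stress and metallothionein genes were also called lower, and adipocyte and mesothelial genes higher. These last 4 calls ended when certain single arrays were left out, among them septic wildtype replicate 1 (oxidative stress and adipocyte lists), 2 (stromal and adipocyte lists) and 4 (plasma cell and stromal lists). The other 11 stood whichever array was left out, but a further quantile normalization ended that for the unfolded protein response. No call stood with an estimated correlation, where the lowest adjusted p was 0.415. Over all genes 0 members of any list passed, and adjusted over the list alone 25 members of the interferon-stimulated list passed, but 0 without septic wildtype replicate 2, where the list's median was -1.28. T cell genes and natural killer cell and cytotoxic genes had small positive medians (0.04 and 0.04) with negative means and test directions.

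If its labels hold, the comparison of septic TLR-deficient with septic wildtype spleens bears on which part of the septic response depends on TLR signalling. Without untreated TLR-deficient mice it cannot tell such a part from a difference between the genotypes that is present without sepsis. Of 23 measured inflammatory cytokines 19, and of 26 chemokines 22, had higher means on the arrays labelled TLR-deficient (adjusted p = 8.50e-05 and 4.44e-06 in camera, and 0.415 for both with an estimated correlation). Il6, the cytokine that drives fever and the acute-phase response, averaged 6.73 ± 2.72 (SD, n = 4) there and 3.57 ± 0.58 (SD, n = 4) on the arrays labelled septic wildtype, a difference of 3.16 with adjusted p = 0.590. The untreated arrays averaged 5.36 ± 2.59 (SD, n = 4) for Il6. Cxcl2, a chemokine that recruits neutrophils, averaged 8.72 ± 2.76 against 5.32 ± 0.87 (SD, n = 4 each), and Il1a, an alarm cytokine released by damaged cells, averaged 8.18 ± 1.75 against 5.30 ± 0.43, a difference of 2.88 (SE 0.81, adjusted p = 0.590). The arrays of a label differed widely, since Il6 stood at 9.06, 8.47 and 6.34 on septic TLR-deficient replicates 1 to 3, at 3.05 on replicate 4 and at 9.22 on the array labelled untreated replicate 4.

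No gene passed between the septic groups in limma (0 of 19938), with 1325 at an unadjusted p under 0.05 and a lowest adjusted p of 0.590. That count was 606 and 716 without septic TLR-deficient replicate 1 or 3, and 2071 and 2201 without septic wildtype replicate 3 or 4, on both sides of the 997 of chance. In 758 genes (3.80%) the labelled groups did not overlap, against 2.86% by chance. Saa3 had a difference of 3.32 (SE 1.26), Ccl3, a chemokine of activated macrophages, of 3.10 (SE 0.99), and Tnip3, a brake on NF-kappaB signalling, of 2.97 (SE 0.99). Cd14, the co-receptor that hands lipopolysaccharide to TLR4, had a difference of 2.62 (SE 1.04), and Ptgs2, the inducible enzyme of prostaglandin synthesis, of 1.96 (SE 0.90). The metallothionein Mt2, which binds zinc and is induced by glucocorticoids and metals, had a difference of 2.54 (SE 0.77), and Mt1 of 2.15 (SE 0.65). Lower means on the arrays labelled TLR-deficient were found for Ccr3, the eotaxin receptor, at 5.32 ± 2.29 against 7.90 ± 0.62, and for Fcer2a at 6.21 ± 2.10 against 8.62 ± 1.10 (SD, n = 4 each). Clec9a, a receptor by which cross-presenting dendritic cells sense dead cells, had a difference of -1.92 (SE 0.95). Slc40a1, the iron exporter of red pulp macrophages, had a difference of -1.76 (SE 0.85), and Cd163, their receptor for haemoglobin and haptoglobin, of -1.56 (SE 0.76). With replicates 1 to 3 of each group only, the alternative chosen after seeing the data, 141 genes passed, 115 higher and 26 lower, and the differences were 4.80 for Cxcl2 and -3.73 for Ccr3.

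**Figure D2:**
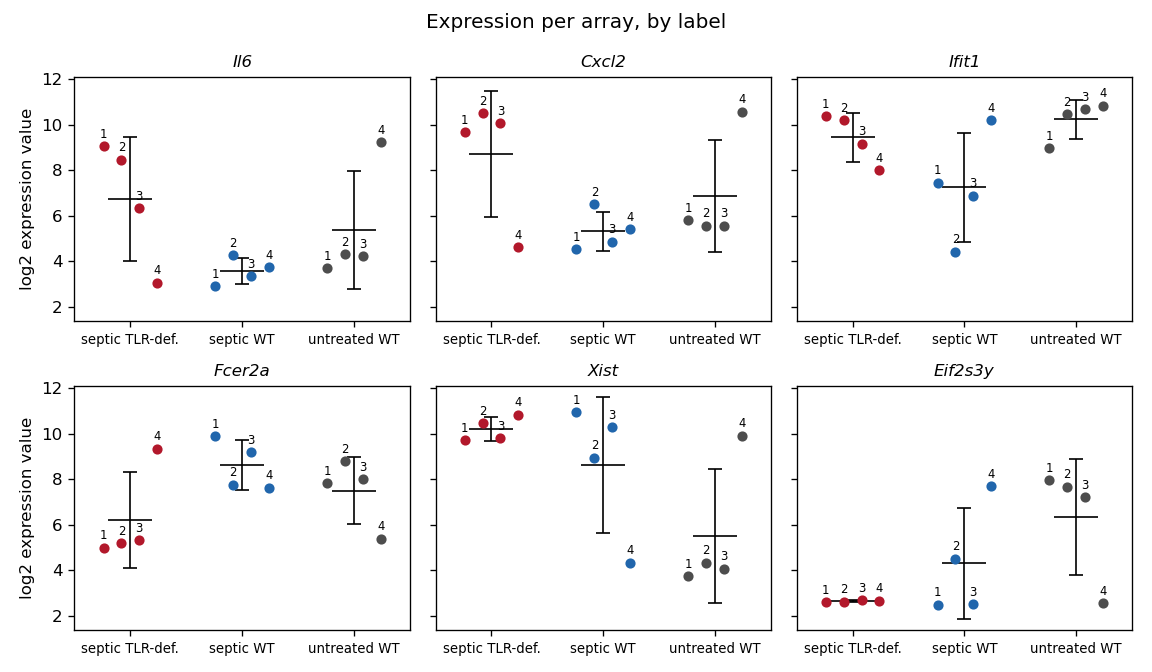
Log2 expression values of 6 genes on each of the 12 arrays, grouped by label, with the replicate number beside each point and bars for the mean ± SD of 4 arrays. Il6 and Cxcl2 are high on septic TLR-deficient replicates 1 to 3 and on untreated replicate 4, where Il6 reads 9.22, and Xist is low on untreated replicates 1 to 3 and on septic wildtype replicate 4.

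Camera called 18 lists higher and 3 lower on the arrays labelled septic TLR-deficient than on those labelled septic wildtype. Cell cycle genes were higher in all 37 members, with a median difference of 0.60 and adjusted p = 3.56e-16 (adjusted p = 0.415 with an estimated correlation). Prc1 and Nusap1, which bundle microtubules in dividing cells, had a difference of 0.98 (SE 0.25) and 0.91 (SE 0.34). All 28 erythroid genes were higher, with a median of 0.57 (adjusted p = 5.91e-08, and 0.450 with an estimated correlation). Without septic wildtype replicate 1, where the list score was -1.15, the median was 0.27. Type I interferon-stimulated genes (1.06), glucocorticoid-responsive genes (0.95), chemokines (0.73), NF-kappaB feedback and target genes (0.72) and apoptosis genes (0.53) had medians over 0.5. The medians were 0.44 for inflammatory cytokines, 0.45 for oxidative stress and metallothionein genes, 0.32 for mitochondrial oxidative phosphorylation genes and 0.27 for hypoxia and glycolysis genes, the last with Pfkfb3, a switch of glycolysis, at 1.68 (SE 0.63; 1.11 without septic wildtype replicate 2). Without septic wildtype replicate 2 the medians were 0.57 for interferon-stimulated genes, 0.40 for NF-kappaB targets, 0.18 for apoptosis genes and 0.14 for oxidative phosphorylation genes. Without septic TLR-deficient replicate 1 they were 0.70 for interferon-stimulated genes, 0.25 for inflammatory cytokines and 0.08 for hypoxia and glycolysis genes. Interferon-stimulated genes had 1.78 without septic wildtype replicate 4, and hypoxia and glycolysis genes 0.43 without replicate 3. The calls of these 11 lists stood whichever single array was left out, but a further quantile normalization ended that for oxidative phosphorylation, and with an estimated correlation no call stood (lowest adjusted p = 0.277). A further 7 lists were called higher and 3 lower, but each of these calls ended without some single arrays. Higher were interferon-gamma-induced GTPases and antigen processing, unfolded protein response and heat shock genes, coagulation, fibrinolysis and complement genes, TLR pathway components, plasma cell genes, acute-phase and antimicrobial genes and cytosolic ribosomal protein genes. Lower were adipocyte and mesothelial genes, B cell genes and pancreatic acinar genes. Leaving out septic wildtype replicate 2 ended all of these except the acute-phase, B cell and acinar calls, leaving out septic wildtype replicate 4 ended the acinar call, and the acute-phase and B cell calls each ended without septic TLR-deficient replicate 1 or 2 or septic wildtype replicate 1 or 3. Adjusted over the list alone, 6 cell cycle genes passed (12 without septic wildtype replicate 2), 3 each of the glucocorticoid and oxidative stress lists and 2 plasma cell genes (0 in each of these without that array), while 0 members passed over all genes.

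**Figure D3:**
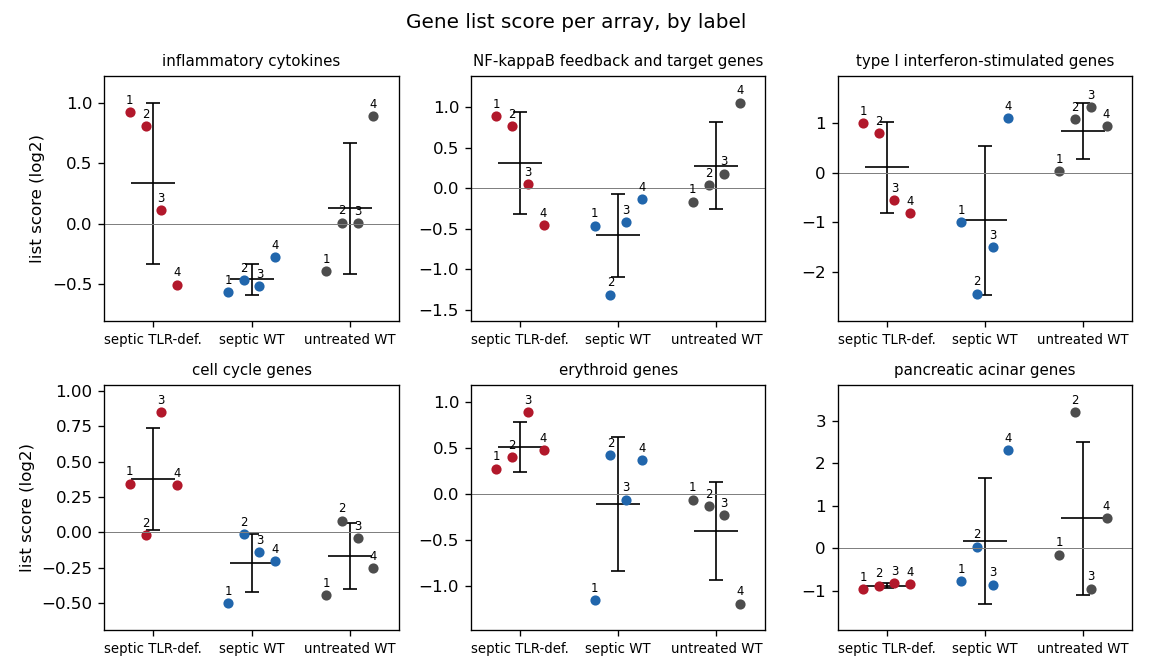
Score per array of 6 gene lists, the mean over members of log2 value minus the gene's mean over the 12 arrays, grouped by label, with replicate numbers and bars for the mean ± SD of 4 arrays. Pancreatic acinar genes stand at 3.22 on untreated replicate 2 and 2.31 on septic wildtype replicate 4, and erythroid genes at -1.18 on untreated replicate 4.

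By the labels, the comparison of septic TLR-deficient with untreated wildtype spleens changes genotype and sepsis together, so it cannot separate them. Erythroid genes were higher in all 28 members on the arrays labelled TLR-deficient, with a median difference of 0.98 and adjusted p = 9.60e-31 (adjusted p = 0.277 with an estimated correlation). Hemgn, a nuclear protein of red cell precursors, averaged 7.93 ± 0.60 against 6.57 ± 0.53 (SD, n = 4 each), and Rhag, a red cell membrane channel, averaged 9.14 ± 0.80 against 7.91 ± 0.60. Cell cycle genes had a median of 0.51 (adjusted p = 3.44e-28, and 0.277 with an estimated correlation), with Rrm2, a subunit of the enzyme that supplies DNA building blocks, at 1.06 (SE 0.34). Pancreatic acinar genes, which encode digestive enzymes, had a median of -1.64 (adjusted p = 1.29e-17, and 0.415 with an estimated correlation), and the list scores of the untreated arrays lay far apart, at -0.15, 3.22, -0.95 and 0.71 for replicates 1 to 4. Without untreated replicate 2 the median was -0.65. Cpb1 averaged 3.95 ± 0.10 against 6.78 ± 3.02 (SD, n = 4 each), a difference of -2.83, and -1.63 without untreated replicate 2.

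No gene passed in limma between these groups (0 of 19938), with 375 at an unadjusted p under 0.05 where chance gives 997, and the lowest adjusted p rounded to 1. Leaving out septic wildtype replicate 2, which enters only through the shared estimate of the spread, brought 1225 genes under an unadjusted p of 0.05 and still 0 past the adjusted threshold. The count was 146 and 576 without septic TLR-deficient replicate 3 or 4, and 193 and 723 without untreated replicate 3 or 4. The labelled groups did not overlap in 678 genes (3.40%), against 2.86% by chance. Cd59a, which shields cells from complement, averaged 7.39 ± 0.76 against 5.48 ± 0.41 (SD, n = 4 each), and Adgre1 had a difference of 2.06 (SE 0.74). Uty, a Y-linked relative of a histone demethylase, had a difference of -3.35 (SE 1.01), and Xist of 4.70 (SE 1.44). Tlr9, the receptor for bacterial DNA, had a difference of -1.11 (SE 0.50). With replicates 1 to 3 only, 33 genes passed, 22 higher and 11 lower.

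In this comparison camera called 5 lists higher and 10 lower on the arrays labelled TLR-deficient, and no call stood with an estimated correlation. Mitochondrial oxidative phosphorylation genes had a median of 0.16 (0.30 without septic TLR-deficient replicate 2, 0.11 without replicate 3 and 0.24 without untreated replicate 2), with Ndufs4, a subunit of respiratory complex I, at 0.75 (SE 0.29). Cytosolic ribosomal protein genes (0.20) and oxidative stress and metallothionein genes were also called higher. Interferon-stimulated genes had a median of -0.77 (adjusted p = 1.36e-09, and 0.459 with an estimated correlation), interferon-gamma-induced GTPases and antigen processing -0.47, B cell genes -0.42 and MHC class II presentation genes -0.39. Without septic TLR-deficient replicate 4 the medians were -0.43 for interferon-stimulated genes and -0.70 for B cell genes, without replicate 3 -0.29 for the interferon-gamma list and -0.24 for B cell genes, and without untreated replicate 4 -0.62 for B cell genes. Among MHC class II genes Cd74, the chaperone of class II molecules, had a difference of -0.46 (SE 0.29), and H2-Oa, which tunes their peptide loading in B cells, of -0.49 (SE 0.42; -0.83 without septic TLR-deficient replicate 4 and -0.27 without replicate 2 or untreated replicate 2). Dendritic cell genes, stromal and endothelial genes and TLR pathway components were called lower as well. So were monocyte genes and natural killer cell and cytotoxic genes, but leaving out any of several single arrays, septic wildtype replicate 2 among them, ended both calls. Neutrophil genes (0.04), platelet and megakaryocyte genes (0.02) and coagulation, fibrinolysis and complement genes (0.01) had positive medians with a negative mean and test direction, and NF-kappaB feedback and target genes (-0.05) had a negative median with a positive mean. The lists of neutrophil, T cell, platelet and megakaryocyte, and red pulp and marginal zone macrophage genes were called in none of the 3 comparisons. Adjusted over the list alone, 2 cell cycle genes and 0 erythroid genes passed, against 14 and 9 without septic wildtype replicate 2. The number of lists called was 23 without septic TLR-deficient replicate 4.

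Between the septic groups, monocyte genes (-0.08) and red pulp and marginal zone macrophage genes (-0.05) had negative medians with a positive test direction. Without septic wildtype replicate 2, red pulp macrophage genes (-0.46), dendritic cell genes (-0.57), MHC class II presentation genes (-0.52) and T cell genes (-0.39) were called lower on the arrays labelled TLR-deficient, and B cell genes had a median of -0.69. With an estimated correlation 0 lists were called without that array in any of the 3 comparisons. Between septic and untreated wildtype spleens, leaving out that array brought calls for cell cycle genes (-0.13) and cytosolic ribosomal protein genes (0.19). The exact two-sided permutation test of the list scores, which compares 4 arrays with 4 and cannot go below p = 0.0286, reached that value for 4 lists between septic and untreated wildtype arrays and for 1 list in each of the other comparisons. Over the 90 list tests the lowest adjusted p of these scores was 0.297.

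The share of the septic wildtype response kept in TLR-deficient spleens was measured on genes that differed by at least 1 (log2) between a pair of septic and a pair of untreated wildtype arrays, with the ratio taken on the other pairs. The median ratio was 0.247, and it ranged from -1.13 to 1.10 over the 36 splits of the wildtype arrays. Genes selected as higher in the septic pair gave a median ratio of 1.20 (range -14.2 to 14.4) and those selected as lower gave 0.243. For the genes selected as higher the septic change on the other arrays was above 0 in only 21 of 36 splits, with a median of 0.04, so their ratio is no share of a response. The range includes both a complete loss and a full retention of the response, so these data set no value for it. Since no gene passed in either of the first comparisons, they shared 0 genes.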

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

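The counts over other splits of the arrays, the test of sex, the counts on spread between animals and the test of signal range were chosen after the results they concern were seen, and the tests on probe sets without a symbol, on random groupings, on tissue of another type and on islet genes before. Neither count on spread between animals decides anything. The earlier one, on inflammatory cytokine scores, took for granted that sepsis raises cytokine transcripts: 0 of the 4 septic wildtype arrays lay above the untreated median, and 3 untreated arrays lay above all of them. The one that replaced it after those values were seen only restates that untreated replicate 4 stood apart, being 1 or more (log2) outside the range of the other untreated arrays on 547 genes, against 75 at most for another.

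In deposited order, with the group borders shifted by 1 place, the 12 arrays form 3 blocks of 4, each array was most correlated with one of its own block, and limma's F test over these blocks called 595 genes (2231 without septic wildtype replicate 2) against 0 over the labelled groups, where 886 genes had an unadjusted p under 0.05. Among 100 random groupings and this one, 1 of 101 called as many genes, with 198 as the highest other count. The blocks were found from the same data, so this count restates their likeness and decides nothing about chance. Between the 2 blocks of arrays that lack Y-linked transcripts, 304 genes differed (1872 without septic wildtype replicate 2). Sex, as far as these transcripts show it, does not separate those blocks, so sex alone does not describe the 3 blocks. The number of genes carries the same limit, since the blocks came from these data. A candidate explanation that stays open is that the labels are displaced by 1 place against the columns of values: its test asked for over 100 of the 12147 probe sets without a symbol and found 5 (0 over the labelled groups), so it missed its own bound, and 642 had an unadjusted p under 0.05, fewer than the 796 with the borders shifted the other way. Low signal alone does not account for that, since at a mean log2 of 5 to 6, 18.7% of genes and 6.89% of these probe sets had such a p. At 7 to 8 the shares were 18.9% and 11.4%. The 0 called over every other placing of the borders cannot show whether these probe sets respond, since 0 genes were called there too. The test thus gave displaced labels no support. It does not exclude them, because these probe sets responded less than genes at both levels, a reason found after the result. The grouping of the arrays and the sex-linked transcripts are what displaced labels could give, but they do not tell which condition each block holds. They suggested the explanation, however, and so cannot test it. The sample titles carry running numbers. Sorted as text instead of by number, the titles change group at the same places as the blocks. In that order the arrays labelled septic TLR-deficient replicates 1 to 3 and untreated replicate 4 would be titled septic wildtype. Septic TLR-deficient replicate 4 and septic wildtype replicates 1 to 3 would be untreated, and the other arrays TLR-deficient. This order was noticed after the blocks were known and was not tested. Spread between animals, single exchanged samples and a trait of the animals that the labels omit stay open too, without a test that decides, and no array was reassigned.

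For septic against untreated wildtype arrays, 35 of the 35 splits of the 8 arrays gave as many genes as the labelled one, which gave 0, and the highest other count was 8. Between the septic groups 35 of 35 splits did, with 0 for the labelled one and 64 as the highest other, and between septic TLR-deficient and untreated arrays 35 of 35 did, with 0 and 217. Since the labelled count was 0 in each, every split gives as many whatever the values, so these counts decide nothing about chance. The split with 217 genes sets septic TLR-deficient replicates 1 to 3 and untreated replicate 4 against the rest, that with 64 sets septic TLR-deficient replicates 1 to 3 and septic wildtype replicate 4 against the rest, and that with 8 sets septic wildtype replicates 1 to 3 and untreated replicate 4 against the rest. The highest counts thus came from splits other than the labelled ones.

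The array labelled septic wildtype replicate 2 stood apart, with a standard deviation of its log2 values of 1.52 where the others of its group had 2.14 to 2.16. Genes under a log2 value of 5 on replicates 1 and 3 of its group were higher on it by 1.01 on average, and for genes over 9 the difference was -1.45. Its values had a slope of 0.490 on the mean of the other arrays, whose own slopes were 0.986 or more. A narrower signal range on the whole array would give such a slope. A low slope and a shift of dim and bright genes also follow in part from a low correlation with the other arrays. By themselves they do not single out that explanation. The lower standard deviation does not follow from a low correlation, and it is itself a narrower spread of values on this array. Its highest value, 13.37, lay within the 13.26 to 13.79 of the others. For tissue or cells of another type in the sample, 0 genes at log2 10 or more lay 2 or more above every other array, against 1 on another array. This test cannot decide, because bright genes read lower on this array and only 118 genes read 10 or more on it (304 to 410 on the others). Untreated replicate 2 did not exceed 1 such gene either, although its pancreatic acinar genes were high. No other biological explanation was tested.

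Pancreatic acinar genes were highest on untreated replicate 2, with a list score of 3.22, and on septic wildtype replicate 4, with 2.31, and 21 of 24 acinar genes (87.5%) lay over 1 (log2) above the median of the other arrays on both. Cpa1, a carboxypeptidase of pancreatic juice, read 11.08 and 9.77 there, and Try5, a trypsin, 10.65 and 9.69, and a smaller rise was seen on untreated replicate 4, with a list score of 0.71, Cpa1 at 7.86 and Try5 at 7.61, and on untreated replicate 1, with Cpa1 at 6.23 and Try5 at 6.14. Pancreatic tissue attached to the spleen may be the source, and its test on 9 islet genes found 0% of them over 0.5 above the median on untreated replicate 2. Islets are a small part of the pancreas, so their absence does not decide it, and attached pancreas cannot be told apart from another source of these transcripts. No other biological explanation was tested.

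Single arrays stood far from the others of their labelled group in 30 of 249 sets of 4 values examined. Chance gives about 1 in 20, but that rate does not apply here, because most of the genes were chosen after their values were seen, for large differences, and they are not independent of each other. On the array labelled untreated replicate 4 these were Il6 at 9.22, Cxcl2 at 10.57, Il1a at 8.99, Ptgs2 at 9.07, Mt1 at 11.78 and Xist at 9.91, all above the other untreated arrays. Below them lay Eif2s3y at 2.55, Uty at 3.07, Kdm5d at 3.03, Ccr3 at 3.33, Cr2 at 7.72 and Slc40a1 at 7.91, and the erythroid list score at -1.18. On the array labelled septic TLR-deficient replicate 4, Fcer2a at 9.35, Clec9a at 7.86 and Klrd1 at 7.91 lay above its group. Cxcl2 at 4.62, Mt2 at 9.23, Mt1 at 8.82, Il1r2 at 4.98 and the glucocorticoid list score at -0.81 lay below it. On the array labelled septic wildtype replicate 4, Kdm5d at 6.55, Cpa1 at 9.77, Try5 at 9.69 and the chemokine list score at -0.064 lay above the group. On septic wildtype replicate 2, Cr2 at 7.37 and the unfolded protein response list score at -0.87 lay below and Nusap1 at 7.09 above the group. The standard deviation of all log2 values on untreated replicate 1, 2.16, lay below the 2.22 of the other untreated arrays.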

How the results depend on the processing

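The settings restricted to replicates 1 to 3 and the Y-linked covariate were chosen after seeing the data, and the others before.

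The count of 0 genes was the same in each comparison under every alternative fixed beforehand, except that array weights gave 1 gene in septic against untreated wildtype, Smoc2, lower by a difference of -0.92. The replicate block gave 0 genes in each, leaving out each array in turn gave 0 to 0, and the Y-linked covariate gave 0. With replicates 1 to 3 only, 9 genes passed for septic against untreated wildtype, 141 between the septic groups and 33 for septic TLR-deficient against untreated. Without septic wildtype replicate 2 as well, the counts were 19, 1002 and 675. The arrays removed were those that stood apart from their labelled groups, which by itself favours calls, so these counts describe the structure of the arrays and are no test of the labels.

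Camera called 15, 21 and 15 lists in these comparisons, and 0 in each with an estimated correlation and 0 in each with fry in place of camera, where the lowest adjusted p was 0.394, 0.357 and 0.394. Leaving out 1 array gave 14 to 20, 17 to 26 and 13 to 23 lists, the highest value of the last without septic TLR-deficient replicate 4. The further quantile normalization gave 14, 17 and 15, the filter at percentile 25 gave 15, 17 and 14, and the replicate block 15, 19 and 15. No called list took the other direction. Centring each array on its median shifted the median difference of all genes by -0.13 for septic against untreated wildtype and by 0.11 between the septic groups, so list medians of that size carry no direction of their own. Why the list calls end was not tested, beyond the correlation that the setting itself changes.

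The median ratio for the response kept was 0.247, and 1.20 for genes that rose, whose septic change was near 0, so that value is no share kept. The ratio over all selected genes was 0.252 at a difference of 2, 0.243 for genes that fell only, 0.112 after quantile normalization, 0.239 with the mean of probe sets and 0.0378 to 0.608 without 1 TLR-deficient array. Beside Myd88 and Ticam1, 0 genes were called with 25, 50 or 100 neighbours each side. Over 52 of the genes named, 123 of 3723 values under alternatives had the other sign, and 100 had an adjusted p under 0.05, none of them under an alternative fixed beforehand.

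Differences from the group mean correlated at a median of -0.113 for equal replicate numbers and 0.0440 for unequal ones, with 3 of 12 pairs over 0.1. These values gave no sign that replicate numbers pair the groups. They cannot exclude it, since arrays standing apart from their labelled groups enter the group means.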

Other observations

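Il1r2, the decoy receptor for interleukin-1 found on neutrophils, read between 7.81 and 8.41 on the 4 arrays labelled untreated. It read 4.88, 5.07 and 5.52 on septic wildtype replicates 1 to 3 and 8.31 on replicate 4. Cr2, the complement receptor of follicular and marginal zone B cells, read 7.86, 7.13 and 7.22 on the arrays labelled septic TLR-deficient replicates 1 to 3 and 10.42 on replicate 4. Klrd1, a subunit of an inhibitory receptor on natural killer cells, read 5.93, 6.05 and 5.92 on the first 3 of these arrays, 7.91 on replicate 4 and 5.38 on the array labelled untreated replicate 4.

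Kcnma1, a potassium channel of smooth muscle and neurons, read 11.71 on the array labelled septic wildtype replicate 4 and 7.29 on septic TLR-deficient replicate 4, and between 3.39 and 6.52 on the other 10 arrays. Its mean difference between septic and untreated wildtype arrays was 1.77 (SE 1.48, adjusted p = 0.471), 2.69 without septic wildtype replicate 3 and -0.04 without replicate 4. Ctrb1, which encodes the pancreatic enzyme precursor chymotrypsinogen, read 10.95 on untreated replicate 2 and 4.51 on untreated replicate 3.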
